A study of Solanum lycopersicum with 12 samples.

How the data were processed

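Shoots and roots of mock-sprayed and PA-sprayed tomato plants were each sampled 3 times, and 4 plants were pooled in each sample, per the labels' protocols. The spray held 300 µM PA and 0.1% Tween 20. Seedlings were transplanted 4 days after germination and grown at 24 °C with 16 h of light. RNA was extracted with a Zymo Plant RNA kit and 2 µg entered a Lexogen QuantSeq 3′ library kit, per the labels' protocols. The submitters' processing notes name FastQC 0.11.8, Trimmomatic 0.38, STAR 2.6.1d and DESeq2, with no version for the last. The read counter, genome build and annotation are not given in the sources used here, nor is how reads shared between similar loci were counted.

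The deposited table holds a normalized signal for 34688 loci in 12 columns, called normalized counts in its title by the authors. How it was normalized is not given in the sources used here beyond the name of DESeq2, and the values behave as gene counts divided by 1 size factor per sample. In each column 100% of values were whole multiples, within 0.01, of the value of 1 read, so whole reads were recovered. Size factors ran from 0.6402 to 1.313. No locus name occurred more than once and every column was used.

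Groups and replicate numbers were taken from the sample titles. The labels describe each sample as a pool of plants and say no more on how pools were kept apart, so p-values measure the spread between these samples. Whether the root and shoot sample of a number came from the same plants is not given in the sources used here. No 2 replicates agreed within sampling noise, as the chi-square per degree of freedom between replicates of a group was 4.071 to 10.71. Same-numbered samples did not deviate together by more than 0.1 in every pair, so the numbers were not treated as pairs.

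Depth was 4214169 to 7386030 reads per library. A count of 0 allows up to 3 reads, and such limits cover counting error only, since molecular identifiers are not given in the sources used here. The 10 most abundant loci took 11.17 to 14.04% of reads in shoot and 7.155 to 8.55% in root.

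The main test was limma 3.58.1 with an intensity trend, in R 4.3.3, on log2(value + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low loci. Loci entered a fit with a mean of at least 10 normalized counts over its samples, or in each tissue for the interaction. Shoot and root were fitted separately, the interaction used all 12 libraries with one mean per group, and mock root was compared with mock shoot. Whole reads were also tested with the edgeR 4.0.16 quasi-likelihood test, which called 237 loci in shoot and 226 in root, 221 and 210 of them shared with limma, and with DESeq2 1.42.0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

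The tests, thresholds, rule for named loci and most alternatives were chosen before the data were examined. By that rule the loci of highest and lowest fold change were taken among those with an adjusted p below 0.05, a mean of at least 50 and groups that did not overlap. The rule was written for 8 in each direction with a product name, and for 2 in each direction where no source pairs identifiers with names, which was the case here. The reference table, of assembly SLM_r2.1, held 0 entries with these identifiers, so 34 lists of pathway and marker genes were not tested. The tissue classes (mean log2 root over shoot of at least 2 or at most -2 over all 12 libraries), the markers (6 on that scale), the second set of markers, chosen in the same way from mock libraries only and used for the bounds on carried-over tissue, and the tests of neighbouring loci were chosen after the data had been seen. Class members were compared with all tested loci by Fisher's exact test, and classes were tested with limma's camera with a preset and an estimated correlation.

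Each fit was tested on simulated counts with 200 changed loci drawn from the real means and library sizes. In shoot, with 14496 loci in the fit, limma recovered 67.7% of 2-fold and 95.9% of 4-fold changes, and 8.09% of calls were false. In root, with 14650 loci, it recovered 83.8% and 100%, and 6.25% were false. The interaction, with 12997 loci, gave 54.6% and 88.5%, and 2.13% were false. For the comparison of mock tissues, with 15324 loci, the values were 77.1% and 93.9%, and 14.9% were false. The simulated loci vary independently, whereas the loci called in the data varied together within groups. The real mock tissues also differed at 10129 loci, far more than the 200 changed here. These rates therefore need not hold for the real calls.

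Alternatives were other pseudocounts (0.5 and 5), no filter or a filter of 50, quantile and median-of-ratios scaling, edgeR, DESeq2, a replicate block, all 12 libraries in one fit, sample quality weights, a 2-fold threshold, and leaving out each library in turn.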

Results

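Piperonylic acid (PA) inhibits cinnamate 4-hydroxylase, the second enzyme of the phenylpropanoid pathway, from which plants make lignin precursors, flavonoids and related phenolics. Tomato seedlings of the cultivar Moneymaker had their leaves sprayed with 300 µM PA or with a mock solution, 7 and 14 days after transplantation, and were harvested on day 15. Messenger RNA of shoots and of roots was measured separately by 3′-end sequencing, which yields reads from the end of each transcript. The 12 libraries formed 4 groups of 3, mock shoot, PA shoot, mock root and PA root, and each sample pooled 4 plants. Libraries held 4214169 to 7127537 reads in mock shoot, 5465342 to 6736313 in PA shoot, 6158777 to 6262275 in mock root and 6065291 to 7386030 in PA root. Of 34688 loci, 10682 had no read in any library. Loci with at least 1 read numbered 18753 ± 429 in mock shoot, 19020 ± 281 in PA shoot, 19749 ± 60.1 in mock root and 19654 ± 209 in PA root (SD, n = 3 each). Replicates of a group correlated at 0.983 to 0.991 across loci, against 0.868 to 0.888 between tissues. These correlations included the loci with no read in any library, which tends to raise them. Loci are not independent replicates. The files do not pair locus identifiers with gene names, so loci are given by identifier, with the chromosome that the identifier carries.

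The comparison of mock-sprayed tissues set the background for the PA effects. Mock roots and mock shoots differed at 10129 of 15317 tested loci, 5147 higher in root and 4982 higher in shoot. Of these, 6149 differed by at least 2-fold, 2941 higher in root and 3208 higher in shoot, and log2 differences ran from -11.30 to 11.40. Markers of each tissue, loci at least 64-fold higher there and with a mean of at least 500 normalized counts in it, both over all libraries, numbered 95 for root and 200 for shoot. The root markers took 4.90 ± 0.32% of reads in mock root and 0.0142 ± 0.0016% in mock shoot, and the shoot markers took 20.2 ± 0.70% in mock shoot and 0.116 ± 0.016% in mock root (SD, n = 3 each). These counts were from limma at an adjusted p below 0.05. Quantile scaling moved the median log2 difference of all tested loci by 0.13 and gave 6028 loci higher in root and 4480 higher in shoot.

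The next comparison asked which shoot transcripts differed after leaves were sprayed with PA. In shoots, 134 loci rose and 95 fell with PA, out of 14505 tested. The rises were larger than the falls. Among the loci that changed, 53 rose and 3 fell by at least 2-fold, the median log2 fold change was 0.90 for those that rose and -0.63 for those that fell, and the full range was -1.10 to 3.11. The loci that fell had the higher levels in mock shoot, with a median of 629.1 normalized counts. The median was 166.1 for those that rose and 112.8 for all tested loci. Mock is one side of the comparison, so its level favours high values among loci that fell and low values among those that rose.

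Solyc08g067360.3 on chromosome 8 rose from 54.5 ± 25.5 to 354 ± 57.4 normalized counts (SD, n = 3), a log2 fold change of 2.80 with a standard error of 0.30 (limma adjusted p = 0.000625). Solyc04g007140.1 on chromosome 4 rose from 29.2 ± 9.10 to 193 ± 36.1, a log2 fold change of 2.71 with a standard error of 0.23 (limma adjusted p = 0.000124). Solyc01g006330.5 on chromosome 1 fell from 112 ± 13.2 to 52.1 ± 8.12, a log2 fold change of -1.09 with a standard error of 0.18 (limma adjusted p = 0.0104). Solyc02g086650.3 on chromosome 2, the most abundant of the 4, fell from 2415 ± 98.1 to 1176 ± 358, a log2 fold change of -1.08 with a standard error of 0.17 (limma adjusted p = 0.00597). All 4 were shoot-enriched, with root means below 10 normalized counts in both treatments, and were not tested in root. With all 12 libraries in one limma fit, the adjusted p was 0.0726 for Solyc01g006330.5, within a range of 0.001615 to 0.0726 over its alternatives, and 0.0756 for Solyc02g086650.3, within 2.57e-07 to 0.0756. Without PA shoot replicate 2 the limma adjusted p of Solyc01g006330.5 was 0.0603.

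**Figure D1:**
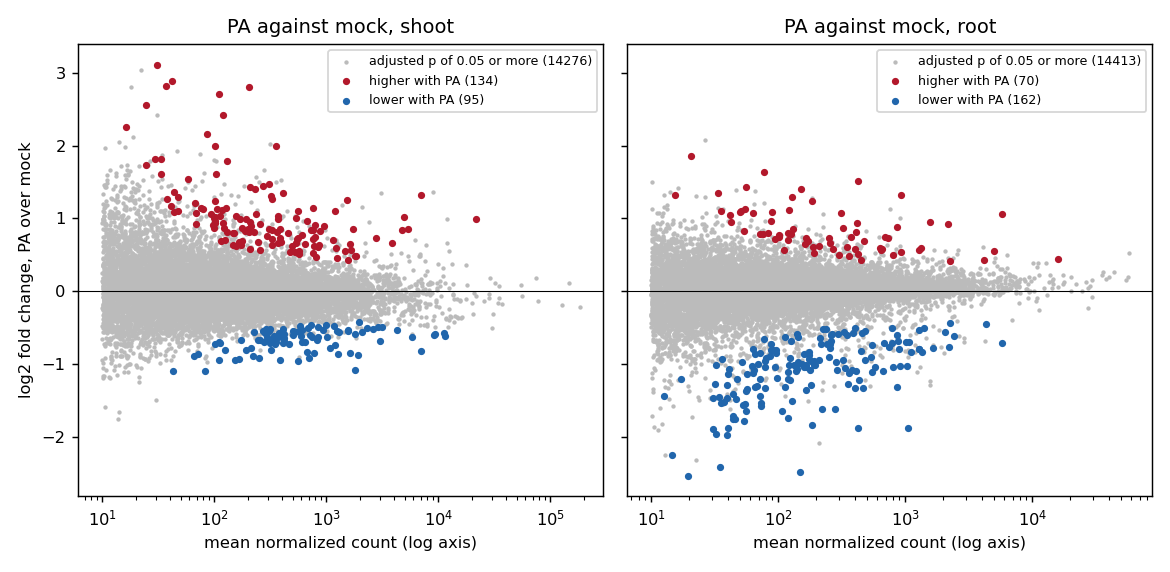
Log2 fold change of PA over mock (vertical axis) against mean normalized count on a log axis (horizontal axis), 1 point per tested locus, for shoot and for root, with loci at a limma adjusted p below 0.05 in colour. In shoot 134 loci lie above 0 and 95 below among those coloured, and in root 70 lie above and 162 below.

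Shoot loci that changed with PA were enriched for loci with a strong tissue preference. Shoot-enriched loci, at least 4-fold higher in shoot than in root over all libraries, made up 51 of the 134 that rose (38.1%) and 32 of the 95 that fell (33.7%), against 14.4% of tested loci. Root-enriched loci, defined in the same way for root, made up 18 of the 134 that rose (13.4%) and 1 of the 95 that fell, against 3.46% of tested loci. Fisher's exact test, two-sided and adjusted over 8 tests, gave odds ratios of 3.71 (adjusted p = 4.28e-11), 3.04 (adjusted p = 4.3e-06) and 4.45 (adjusted p = 2.23e-06) for the first 3 of these. For the last it gave 0.295 (adjusted p = 0.355). This test takes loci as independent, which loci that vary together are not. Stratified by mean level, the first 3 odds ratios were 3.26, 2.14 and 8.81. The classes drew on all 12 libraries, so a rise with PA in shoot moves a locus toward the shoot-enriched class. With classes from mock libraries only, the first 3 odds ratios were 3.03, 3.33 and 4.28. That choice has its own bias, since low values in mock shoot favour the root-enriched class and also a rise with PA. High values there favour the shoot-enriched class and also a fall. As a whole class, the 502 root-enriched loci shifted upward in shoot, with a median log2 fold change of 0.11 and a camera adjusted p of 0.0016, or 0.0141 with an estimated correlation. The 2093 shoot-enriched loci had a median of -0.09, with a camera adjusted p of 0.0966, or 0.00856 with an estimated correlation. Root markers took 0.0155 ± 0.004% of reads in PA shoot against 0.0142 ± 0.0016% in mock shoot (SD, n = 3, two-sided exact permutation p = 0.8), and shoot markers took 18.6 ± 0.15% against 20.2 ± 0.70% (exact permutation p = 0.1, the smallest that 3 against 3 samples allow). Choosing markers over all libraries keeps out loci that PA raised in the other tissue. With 98 root markers chosen from mock libraries only, a choice that favours low values in mock shoot, the share was 0.0134 to 0.0158% in the mock shoot libraries and 0.0168 to 0.0233% in the PA shoot libraries. The enrichment of root-enriched loci among those that rose did not pass with no filter on low values (odds ratio 1.64, Fisher's exact p = 0.0505) or with the class set at 2-fold (1.49, p = 0.0851). Shoot-enriched loci among those that fell had an odds ratio of 1.61 without PA shoot replicate 3 (Fisher's exact p = 0.0984) and 6.65 without PA shoot replicate 1, and among those that rose the odds ratio was 5.99 without PA shoot replicate 2.

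The number of shoot loci that changed, and how they split, depended on single libraries. It was 383 without mock shoot replicate 1, 130 without mock shoot replicate 2, 76 without PA shoot replicate 1 and 62 without PA shoot replicate 2, against 229 with all 6 libraries. In the same order 225, 96, 57 and 52 were higher and 158, 34, 19 and 10 lower, and without mock shoot replicate 3 the split was 209 higher and 76 lower. DESeq2 on whole reads gave 367 and sample quality weights in limma gave 370. Mock shoot replicate 1 stood apart on the first principal component, which held 42.2% of the variance, at -51.1 against -3.61 to 22.4 for the other 5 libraries. Of the 229 loci, 224 also passed without it.

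The effect of the same leaf spray was then measured in roots. In roots 70 loci rose and 162 fell with PA, out of 14645 tested, so falls outnumbered rises. The falls were also larger. Among the loci that changed, 20 rose and 89 fell by at least 2-fold, the median log2 fold change was 0.78 for those that rose and -1.02 for those that fell, and the range was -2.53 to 1.86. The median level in mock root was 160.2 normalized counts for loci that rose and 216.9 for loci that fell, against 99.21 for all tested loci.

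Solyc01g106605.1 on chromosome 1, a root-enriched locus, rose from 216 ± 8.89 to 632 ± 173 normalized counts (SD, n = 3), a log2 fold change of 1.51 with a standard error of 0.16 (limma adjusted p = 0.00352). It had 0 reads in each of the 6 shoot libraries, which allows up to 3 reads in each, or 2.76 to 4.69 normalized counts. Solyc02g086700.5 on chromosome 2 rose in root from 39.1 ± 19.7 to 116 ± 24.9, a log2 fold change of 1.64 with a standard error of 0.31 (limma adjusted p = 0.0294). Its shoot values were 74.1 ± 19.2 in mock and 41.8 ± 11.8 in PA, a log2 fold change of -0.81 that did not pass (limma adjusted p = 0.138). Solyc10g050970.1 on chromosome 10 fell from 246 ± 69.9 to 51.7 ± 42.5, a log2 fold change of -2.48 with a standard error of 0.42 (limma adjusted p = 0.0206). Solyc01g108240.4 on chromosome 1 fell from 1598 ± 564 to 490 ± 360, a log2 fold change of -1.89 with a standard error of 0.38 (limma adjusted p = 0.0374), and it also fell in shoot, by 0.56 on the log2 scale (limma adjusted p = 0.0196). The root call of Solyc01g108240.4 was lost with a filter of 50 (limma adjusted p = 0.0513), with edgeR (0.0568) and with DESeq2 (0.143), and over all its alternatives the adjusted p ran from 0.000193 to 0.162. Without 1 library, adjusted p from limma passed 0.05 for Solyc02g086700.5 (mock root replicate 2, 0.0868; PA root replicate 1, 0.0801; PA root replicate 2, 0.0793), for Solyc10g050970.1 (mock root replicates 2 and 3, 0.0906 and 0.104; PA root replicates 1 and 2, 0.0649 and 0.0793) and for Solyc01g108240.4 (the same 4 libraries, 0.133, 0.162, 0.119 and 0.160).

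**Figure D2:**
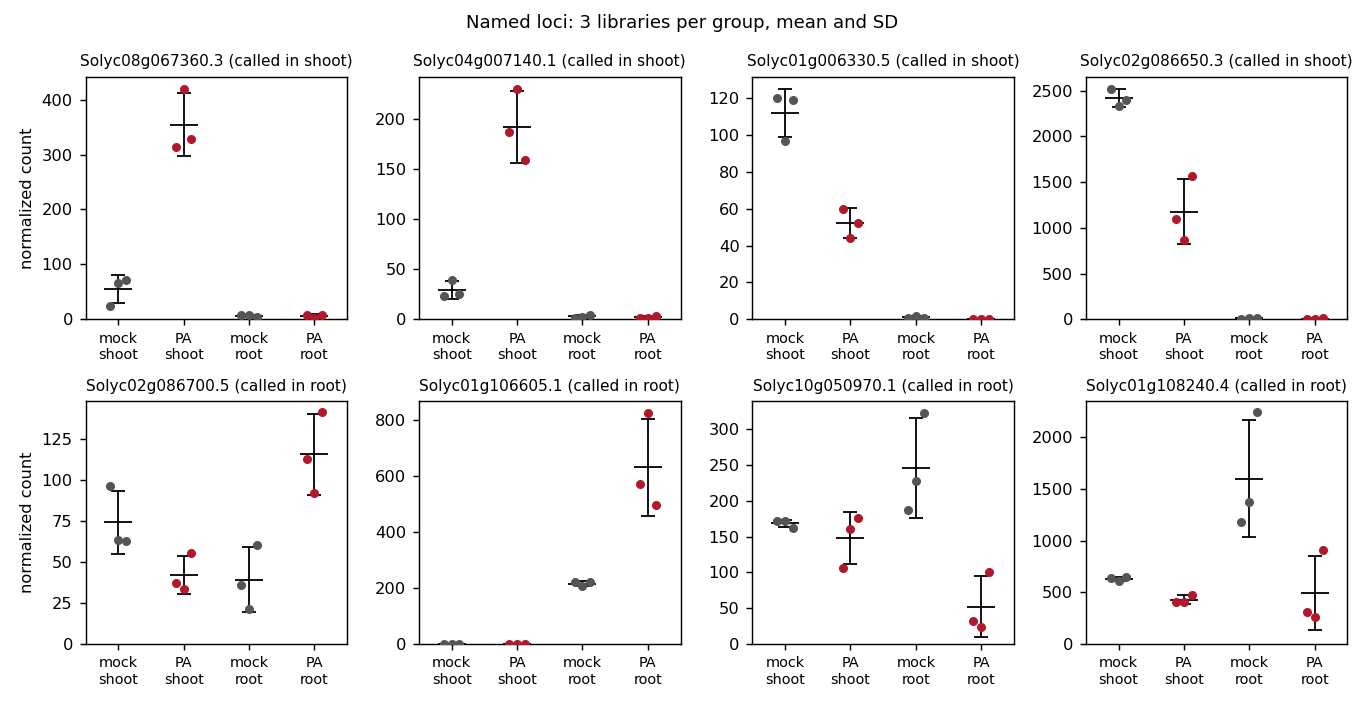
Normalized counts (vertical axis, linear and from 0) of the 8 loci given by identifier, 4 called in shoot and 4 called in root, in each of the 4 groups, with 1 point per library and bars for the mean and SD of 3 libraries. Mock and PA values of the tested tissue do not overlap, as the rule for naming loci requires; at Solyc04g007140.1 the means were 29.2 and 193.

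Roots also showed a tissue preference, in the loci that rose. Root-enriched loci made up 38 of the 70 that rose (54.3%), against 11.4% of tested loci, an odds ratio of 9.40 (two-sided Fisher's exact test, adjusted p = 1.83e-17 over 8 tests). A rise with PA in root itself moves a locus toward this class, as classes drew on all 12 libraries. With classes from mock libraries only, the odds ratio was 7.95. Fisher's exact test takes loci as independent here too. Among the 162 that fell, 13 were root-enriched and 11 shoot-enriched, shares of 8.02% and 6.79% against 11.4% and 6.97% of tested loci, and neither passed this test (adjusted p = 0.341 and 1.00), and 138 were in neither class. Shoot-enriched loci were 7 of the 70 that rose (adjusted p = 0.387). As a whole class, neither passed camera in root (adjusted p = 0.345 for both, and 0.727 with an estimated correlation). Shoot markers took 0.153 ± 0.045% of reads in PA root and 0.116 ± 0.016% in mock root (SD, n = 3, two-sided exact permutation p = 0.3), and root markers 5.18 ± 0.13% and 4.90 ± 0.32% (exact permutation p = 0.3). With 213 shoot markers chosen from mock libraries only, the share was 0.106 to 0.139% in the mock root libraries, and 0.203 and 0.175% in PA root replicates 2 and 3, with replicate 1 inside the mock range. Without mock root replicate 3 the odds ratio of root-enriched loci was 15.6, and all 5 loci that rose without mock root replicate 2 and all 9 without PA root replicate 2 were root-enriched.

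**Figure D3:**
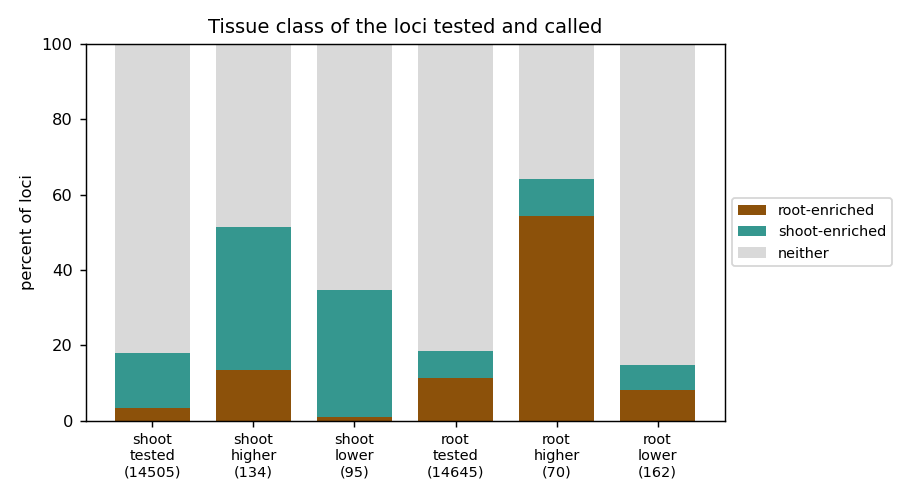
Stacked bars of the percent of loci (vertical axis, from 0) that were root-enriched, shoot-enriched or neither, among all tested loci, those higher and those lower with PA, in shoot and in root, with the number of loci under each bar. In root, 54.3% of loci that rose were root-enriched against 11.4% of tested loci.

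The root count depended on single libraries. It was 262 without mock root replicate 1, 14 without mock root replicate 2 and 15 without mock root replicate 3, against 232 with all 6. Without PA root replicates 1, 2 and 3 it was 79, 18 and 517. DESeq2 on whole reads gave 389 and sample quality weights in limma gave 402. The larger number of falls was lost in 3 of these, with 42 higher and 37 lower without PA root replicate 1, 9 and 9 without PA root replicate 2, and 9 and 6 without mock root replicate 3.

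Whether the PA effect differed between the 2 tissues was tested directly as an interaction over all 12 libraries. The PA effect differed between root and shoot at 49 of 13010 tested loci, with the root effect higher than the shoot effect at 12 and lower at 37. The estimates had opposite signs in the 2 tissues at 43 of the 49, and 31 of the 49 were among the loci that rose in shoot. Choosing loci for a large difference favours estimates of opposite sign, so the 43 do not show that PA acted in opposite directions. Solyc02g086700.5, which rose in root, had a root effect higher than its shoot effect by 2.45 on the log2 scale, with a standard error of 0.44 (limma adjusted p = 0.0246). For Solyc10g050970.1 and Solyc01g108240.4 the difference between tissues did not pass (limma adjusted p = 0.0872 and 0.266). Of the 49 loci, 33 had passed in shoot alone, 6 in root alone, 2 in both and 8 in neither. The count was 85 without mock shoot replicate 3, 24, 15 and 30 without PA shoot replicates 1, 2 and 3, 15 without mock root replicate 2, and 74, 24 and 160 without PA root replicates 1, 2 and 3. The direction turned without PA root replicate 1, where the root effect was higher at 43 loci and lower at 31. DESeq2 on whole reads gave 177, 63 with the root effect higher and 114 lower, and edgeR gave 75.

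The last comparison asked whether the same loci responded in both tissues. Of the 13010 loci tested in both, 6 rose in both tissues and 13 fell in both, where independent lists of the same sizes would share 0.424 and 0.970. Only 2 rose in shoot and fell in root, against 1.34 for independent lists, and 0 fell in shoot and rose in root, against 0.306. One-sided Fisher's exact tests, adjusted over 4, gave p = 7.58e-06 for shared rises, 4.72e-11 for shared falls, and 0.52 and 1.00 for the opposite pairs. These tests take loci as independent. When the loci called in one tissue were tested as lists in the other, no list passed camera with an estimated correlation. The camera adjusted p was 0.578 and 0.19 in root for those that rose and fell in shoot. It was 0.0904 and 0.412 in shoot for those that rose and fell in root. With limma's fry, which tests a list by itself, only those that rose in root passed, in shoot (adjusted p = 0.0201). For the other lists fry gave 0.269 and 0.102 in root for those that rose and fell in shoot. It gave 0.205 in shoot for those that fell in root. Across all loci the fold changes of the 2 tissues were nearly unrelated (Pearson 0.0697, Spearman 0.072), while across the 198 loci called in shoot Pearson was 0.422 and across the 200 called in root 0.367; these are correlations across loci, which are not independent replicates. The 2 comparisons share no library, but whether same-numbered roots and shoots came from the same plants is not given in the sources used here. If they did, differences between plants apart from PA could enter both lists. The number of loci that changed the same way, 19, was 32 without mock shoot replicate 1, 8 without mock shoot replicate 2, 4 without PA shoot replicate 1 and also 4 without PA shoot replicate 2. It was 0 without mock root replicate 2 or 3, where root had 14 or 15 calls, 12, 2 and 39 without PA root replicates 1, 2 and 3, and 116 with calls at an unadjusted p below 0.01, where independent lists would share 18.5 and 19 loci changed in opposite directions.

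**Figure D4:**
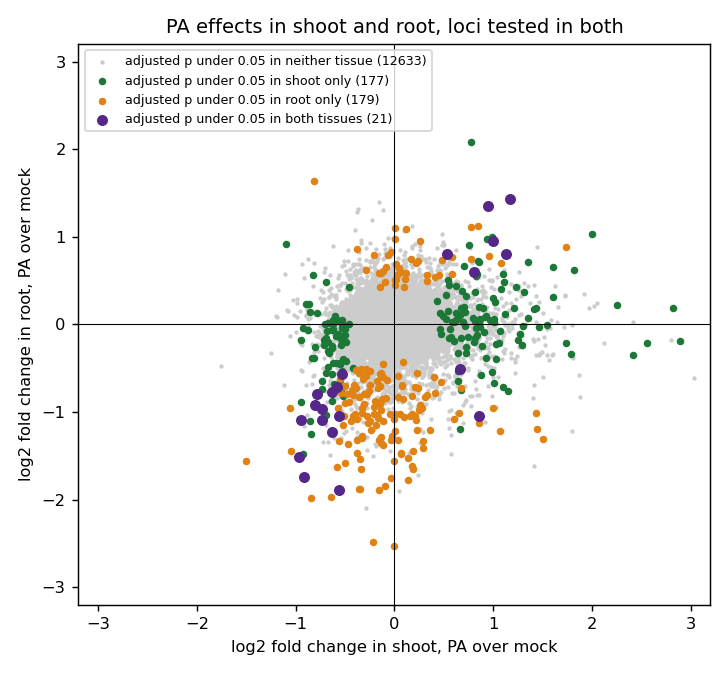
Log2 fold change of PA over mock in root (vertical axis) against that in shoot (horizontal axis), 1 point per locus tested in both tissues, coloured by where it passed. Of the 21 loci called in both tissues, 19 lie in the 2 quadrants of equal sign.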

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

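Of the tests in this part, the splits of the interaction and of the mock tissues were planned before their results were seen, and those of the shoot and root counts were chosen after.

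The PA effect differed between root and shoot at 49 loci, by a direct test of the difference in limma. At 37 of them the root effect was the lower one, and at 43 the estimates had opposite signs. Choosing loci for a large difference favours opposite signs, and only 2 of the 49 had passed in both tissues. Without PA root replicate 1 the direction turned, with the root effect higher at 43 loci and lower at 31. Of 100 splits of the 6 shoot and the 6 root libraries, 3 gave as many loci, the real one included, and the highest of the others gave 62. Both other splits that gave as many kept the real treatment split in one tissue, so they carry that tissue's PA effect. The 83 splits that changed both tissues gave at most 1 locus. Exchanging mock and PA in root alone, which was not among the splits drawn and adds the effects of the 2 tissues in place of subtracting them, gave 351. The share of splits with as many loci was under the 0.05 set beforehand, but this cannot decide whether effects differ between tissues. Splits that change both tissues mix PA and mock libraries, which removes any PA effect along with a difference between tissues. They show that the count depends on the PA labels, and some splits that kept the real labels in 1 tissue did reach the count. The count itself moved between 15 and 160 as single libraries were left out. It was 85 without mock shoot replicate 3, 24, 15 and 30 without PA shoot replicates 1, 2 and 3, and 15 without mock root replicate 2. Without PA root replicates 1, 2 and 3 it was 74, 24 and 160.

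Solyc02g086700.5 had a root effect that exceeded its shoot effect by 2.45 on the log2 scale, with means of 39.1 and 116 normalized counts in mock and PA root and 74.1 and 41.8 in mock and PA shoot. The shoot change did not pass (limma adjusted p = 0.138). The root call was lost without mock root replicate 2, PA root replicate 1 or PA root replicate 2. This locus was named for its large rise in root, which favours a large difference.

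For the single comparisons, 3 against 3 libraries make 10 splits, too few for a share below 0.05. In shoot the real split gave 229 loci and the highest other 1, with 1 of 10 splits as large. In root the values were 232 and 0, again with 1 of 10, and for mock root against mock shoot 10129 and 0, with 1 of 10. Groups of 3 are too small for the test of single samples far from their group.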

How the results depend on the processing

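The settings that left out a library for loci shared between tissues, and the settings of tissue classes and neighbouring loci, were chosen after seeing the data; the others were planned. The number of loci that differed between mock tissues stayed within 1.5 times under the pseudocounts, filters, scalings, edgeR, DESeq2 and replicate block, from 7564 with a filter of 50 to 11856 with no filter, and from 9144 to 10101 without 1 library; 6149 differed by at least 2-fold, and quality weights and the fit of all 12 libraries were not run for it. In shoot (229 loci) DESeq2 gave 367, sample quality weights 370, and a 2-fold threshold 56. In root (232) the same settings gave 389, 402 and 109. All 12 libraries in one fit gave 185 in shoot and 182 in root, and 124 of the 229 and 141 of the 232 loci were among them. For the interaction (49) edgeR gave 75 and DESeq2 177. For loci changed the same way in both tissues (19), an unadjusted p below 0.01 gave 116, against 18.5 for independent lists. Without 1 library the counts ran from 62 to 383 in shoot (383 without mock shoot replicate 1, 130 without mock 2, 76 without PA 1, 62 without PA 2), from 14 to 517 in root (14 and 15 without mock root replicates 2 and 3, 79, 18 and 517 without PA 1, 2 and 3), from 15 to 160 for the interaction (85 without mock shoot 3, 24, 15 and 30 without PA shoot 1, 2 and 3, 15 without mock root 2, 74, 24 and 160 without PA root 1, 2 and 3) and from 0 to 39 for shared loci (32 and 8 without mock shoot 1 and 2, 4 without PA shoot 1 or 2, 0 without mock root 2 or 3, 12, 2 and 39 without PA root 1, 2 and 3). The cause was not tested. Pseudocounts, filters and both other scalings kept the shoot, root and interaction counts within 1.5 times; for shared loci a pseudocount of 5 gave 21, and filters and scalings were not run. Of 136 combinations of a named locus and a setting, 119 kept the direction and the call. Another 17 kept the direction and lost the call, and 0 reversed. A reversal could not occur without 1 library, as the naming rule requires groups that do not overlap. Filters, the replicate block and the fit of all 12 libraries leave the fold change as it was. The 0 therefore says little, and only the call was free to vary in these settings. The alternatives for gene lists were not run, since no names were at hand. At these depths 2-fold changes were recovered less often than 4-fold ones on simulated counts.

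With the replicate number as a block, the counts were 376 in shoot, 441 in root, 110 for the interaction and 10117 for the mock tissues, and 229 of the 229 shoot loci and 231 of the 232 root loci also passed. With the plant pool as a random block the interaction gave 59. Correlations of deviations between same-numbered samples were 0.103, 0.0894 and 0.0335 for shoot and 0.109, -0.0706 and 0.0673 for root, and PA shoot replicate 3 and mock root replicate 2 each correlated best with a sample of another number (0.0368 and 0.12), so the numbers were not taken as pairs between treatments. Between tissues, each mock sample correlated best with its own number (0.0554, 0.0643 and 0.105), a hint from the data, while PA samples gave 0.0129, -0.0534 and 0.0457; whether same-numbered roots and shoots came from the same plants stays open.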

Other observations

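The counts of root loci under other scalings and without single libraries were planned; the other tests in this part, and the use of those counts to weigh explanations, were chosen after the results had been seen.

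In 3 of the 4 sets of loci that changed with PA, members lay beside each other on the chromosomes more often than by chance placement; the shoot loci that fell were the exception. Among the 134 shoot loci that rose, 11 pairs were consecutive tested loci in identifier order, against a mean of 1.24 under permutation, and the 22 loci formed 11 runs of 2 on 7 chromosomes. Among the 70 root loci that rose there were 9 pairs against 0.332, in 5 runs that held 14 loci, the longest a run of 4 on chromosome 8 with log2 fold changes of 0.70 to 1.09, and runs of 3 on chromosomes 3 and 10. Root loci that fell formed 7 pairs against 1.76, and the 95 shoot loci that fell formed 0 against 0.624 (permutation p = 1). Permutation p was 1e-04 for both sets that rose, the smallest that these permutations can give, and 0.0025 for root loci that fell, or 2e-04, 2e-04 and 0.00333 adjusted over 4. Chance placement seldom gave as many pairs in these 3 sets, the largest permutation p being 0.0025. For root loci that fell, the highest count under permutation was 9, above the 7 seen. The permutations moved calls over all tested loci without regard to level or tissue class, so they do not allow for neighbours alike in these. No single chromosome passed a test for an excess or lack of changed loci (smallest adjusted p 0.652). A candidate explanation is that neighbouring loci respond together to PA, and reads shared between near-identical neighbours stay open, since no sequence of these loci was used here. With a filter of 50 the root loci that fell formed 4 pairs, and with DESeq2 19.

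Root-enriched loci were over-represented among shoot loci that rose. Root material in the PA shoot samples was argued against, since root markers chosen from mock libraries only allow at most 0.523% of root RNA in a PA shoot library (0.455% with those chosen over all libraries, a choice that lowers this bound), whereas the 18 loci need 2.40 to 28.9%, with a median of 8.64%. Library scaling was argued against too, as the smallest odds ratio under the other scalings was 4.20. What stays open, as a hypothesis, is that PA may raise in shoot some loci that roots normally express more, and this was not tested beyond the design; without a low-value filter the odds ratio was 1.64.

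Root loci that fell outnumbered those that rose. Scaling was argued against, since at most 32.9% of calls were higher under any scaling tried, and so was dilution by shoot material, since shoot markers chosen from mock libraries only allow at most 0.913% of it in a PA root library (0.872% with those chosen over all libraries), against 50.7% needed for the median fall. The 162 loci also varied together within groups, with a mean correlation of 0.488 against at most 0.0221 in 200 random lists of matched level, and the other sets also exceeded theirs, at 0.292 against 0.0543 for root loci that rose, 0.301 against 0.144 for shoot loci that fell and 0.139 against 0.0614 for shoot loci that rose. Their mean log2 level was 7.72, 7.88 and 8.04 in the mock libraries and 6.63, 6.58 and 7.15 in the PA libraries. A shared state of the plants that varied apart from PA may therefore account for the skew, and with 3 samples per group it cannot be told apart from an effect of PA, so PA stays untested against it; the split was 42 higher and 37 lower without PA root replicate 1, 9 and 9 without PA root replicate 2, and 9 and 6 without mock root replicate 3.

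Loci chosen in one tissue were also tested in the other. The 83 loci that fell in shoot had a median log2 fold change of -0.27 in root, with 64 of them below 0 (camera adjusted p = 1.9e-13, or 0.19 with an estimated correlation). The 48 loci that rose in root had a median of 0.11 in shoot, with 36 above 0 (camera adjusted p = 1.82e-05, or 0.0904 with an estimated correlation). The 152 that fell in root had a median of -0.16 in shoot (camera adjusted p = 2.92e-05, or 0.412 with an estimated correlation), and the 115 that rose in shoot 0.06 in root (adjusted p = 0.188, or 0.578).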
